A study of Mus musculus with 9 samples.

How the data were processed

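Gene expression was measured in colonic mucosa of male mice aged 6 weeks with 9 Affymetrix mouse expression arrays of 45101 probe sets each. Per the labels, 3 arrays came from wild-type mice (WT), 3 from mice lacking the gastrin gene (Gas-/-, named GasKO here) and 3 from transgenic mice carrying hGAS, all on a C57BL/6 background. Per the labels' protocols, the mucosa was separated by injecting PBS into the submucosa, RNA was purified with Trizol, and biotin-labelled cRNA was made by a one-cycle protocol. The deposited values are on the log2 scale, and per the submitters' processing notes they were made with GCRMA, whose version was not stated. GCRMA corrects background from probe sequence, normalises arrays by quantiles and summarises each probe set. The scanner files were not used here.

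The values ran from 0.881 to 15.1, with array medians between 4.13 and 4.16. Gene symbols came from the platform's probe annotation. It paired 34958 probe sets with 1 gene, 932 with several genes and 9160 with none, and 64 were controls. Of the probe sets with 1 gene, 34754 were matched by Entrez number to a RefSeq gene table of assembly GRCm38, and no symbol changed. The files name no genome build, so the gene table served only for names and for which genes neighbour each other. Each of the 18194 genes was represented by its probe set with the highest mean over all 9 arrays. Genes were tested if at least 3 arrays reached a log2 value of 4, which left 11274 genes.

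Genes were compared with limma 3.58.1 in R 4.3.3, with files read by data.table version 1.17.8. A linear model with genotype as its only term was fitted to all 9 arrays with lmFit and eBayes with a mean-variance trend. All 3 pairwise contrasts were taken from this fit, and a moderated F test covered the 3 genotypes together. The fit had 6 residual degrees of freedom per gene and a prior worth 3.47 more. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the 11274 genes, and a gene was called at an adjusted p under 0.05. No label says explicitly that replicates were separate mice, so the p-values measure the spread between these samples. The number of arrays limits the precision.

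Gene lists for pathways, cell types and colon regions numbered 44 and held 741 entries, of which 672 were matched by symbol, or by an older name that is no current symbol of another gene. The 37 lists with at least 5 genes tested were compared with all other genes by camera, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. Members were also counted after adjusting over the list alone. A list's score in an array is the mean over its genes of the log2 value minus the gene's mean over the 9 arrays.

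Groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names first Gast, then per comparison the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap. It adds up to 4 members with the smallest p from each list that was called or held at least 2 called members. Predicted genes without a name were passed over. A group mean under log2 4 is described as near background, and folds against it depend on the background level.

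Before use, the fit was tested on simulated data with 11274 genes for GasKO vs WT. Of 50 genes each changed by log2 0.5, 1, 2 and 3, it called 68%, 94%, 100% and 100%, with 12 false calls. With no change simulated in hGAS vs WT it made 0 calls.

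GasKO vs WT and hGAS vs WT share their WT arrays, so their overlap was set beside 100 simulations. In each, all 9 arrays were drawn anew with no change and each gene independently. Both simulated groups were compared with the same 3 simulated WT arrays. Alternatives covered the filter, quantile normalisation and median centring of the arrays, the choice of probe sets, the eBayes settings, array weights, fits to 6 arrays, thresholds, a block for the replicate number, and leaving out each array in turn. A regional score as a covariate was added after seeing the data. Other splits of the arrays into groups were also fitted. Probe sets with several genes or none were left out of the main tests and tested once in a separate fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.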

Results

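Expression in colonic mucosa was measured on 9 arrays, with 3 arrays each for WT, GasKO and hGAS mice aged 6 weeks. The array medians lay between 4.13 and 4.16 on the log2 scale, and between 50.8% and 51.0% of probe sets reached log2 4 on each array. The series title links the work to proliferation that depends on progastrin, the precursor that the gastrin gene encodes. The targeted gene, Gast, was at background in every group, at 1.96 ± 0.02 in WT, 2.08 ± 0.08 in GasKO and 1.95 ± 0.01 in hGAS (log2, mean ± SD, n = 3 each). That probe set therefore checks neither the knockout nor the transgene, which is of human sequence by its name. Of the gastrin list only Anxa2, a progastrin binding protein gene (13.26 in WT, log2 change 0.03 in GasKO vs WT, adjusted p = 0.83), and Cpe, a prohormone processing enzyme gene (11.91, -0.02, adjusted p = 0.93), passed the filter. Xist, which is expressed from an inactive X chromosome, was at background on all 9 arrays, with group means of its probe sets between 1.90 and 2.72, and all mice were labelled male.

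The GasKO arrays stood apart from the other 6. The first principal component held 53.9% of the variance, with GasKO arrays between 25.8 and 30.1 and the others between -19.2 and -8.38. The second component held 18.1%, with WT replicate 3 farthest out at 24.95 and WT replicates 1 and 2 at 6.95 and 7.72. All GasKO arrays (-4.90 to 0.064) and hGAS arrays (-16.1 to -3.11) lay below the WT arrays. Correlations across the genes tested were 0.990 to 0.996 within groups, 0.971 to 0.983 between GasKO and the other groups, and 0.981 to 0.992 between hGAS and WT. The log2 difference between the 3' and 5' probe sets of actin was 0.826 ± 0.063 in WT, 0.898 ± 0.035 in GasKO and 0.905 ± 0.030 in hGAS (SD, n = 3), and that of Gapdh was -0.159 ± 0.019, -0.105 ± 0.015 and -0.102 ± 0.045. The Gapdh difference was lower in all WT arrays (-0.176 to -0.138) than in all GasKO arrays (-0.117 to -0.0885), so this sign of RNA quality separated those groups too.

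**Figure D1:**
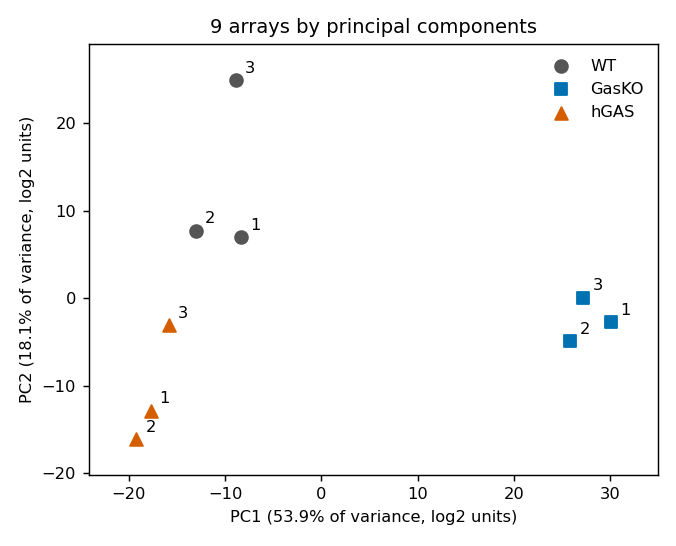
Principal components of the 9 arrays over the genes tested, with PC1 (53.9% of variance) against PC2 (18.1%) in log2 units; each point is 1 array, numbered by replicate. GasKO arrays lie at 25.8 to 30.1 on PC1 and all others below -8.

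Single genes of varied function changed most in mucosa without gastrin. Lpo, which encodes lactoperoxidase, rose 164-fold from 5.57 ± 0.69 in WT to 12.93 ± 0.05 in GasKO (log2, SD, n = 3). Cap1, a regulator of actin filaments, rose 33.1-fold from 6.71 ± 0.15 to 11.76 ± 0.05. The steroid dehydrogenase gene Hsd3b3 fell 8.37-fold from 9.12 ± 0.39 to 6.05 ± 0.38, and Aadac, a lipid esterase gene, fell 15.2-fold from 9.42 ± 0.25 to 5.50 ± 0.33. Interferon response and MHC class II genes rose as lists, while ribosome biogenesis and S phase genes fell by smaller amounts, and none of these calls held with an estimated correlation (adjusted p = 0.627, 0.363, 0.567 and 0.567).

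The comparison asks what goes with loss of the gastrin gene. It called 1366 of 11274 genes, of which 748 rose and 618 fell, with a median absolute log2 change of 0.49. At least a 2-fold change was seen in 139 of the genes that rose and 105 of those that fell. The 3 GasKO arrays did not overlap the 3 WT arrays in 31.1% of genes tested, where chance gives 10%.

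The other large rises included St6galnac1, a sialyltransferase gene, at 75.6-fold, and Hsd17b13, a lipid droplet enzyme gene, at 39.2-fold, both from near background in WT. Gdpd3 rose 23.9-fold (log2 4.58, SE 0.11) and Hddc3 12.7-fold (log2 3.67, SE 0.09). The keratin gene Krt12 rose 13.2-fold and Serpina1b, an alpha-1-antitrypsin gene, 11.9-fold, again from near background. The immunoglobulin light chain genes Igk and Iglv1 rose 34.7-fold (SE 0.49 in log2) and 16.6-fold (SE 0.81). Zan, which encodes the sperm protein zonadhesin, fell 52.7-fold from 7.58 ± 0.29 to background at 1.86 ± 0.03 (log2, SD, n = 3). Zfp945 fell 27.3-fold, though its change was 1.46 in the opposite sense when only probe sets designed for 1 transcript were used. Tnfsf13os fell 19.7-fold, the probe set annotated to Mir1931 14.8-fold, Galc, the galactosylceramidase gene, 11.2-fold and Hsd3b2 8.80-fold, each to near background in GasKO. Hspb7, a small heat shock protein gene, fell 8.53-fold from 7.63 ± 0.18 to 4.53 ± 0.46, and Mid1 fell 7.70-fold. All 20 of these genes kept their call when any 1 array was left out, but several values depended on the probe set. With a gene's probe sets averaged, the log2 change was 3.20 for St6galnac1, 2.65 for Hsd17b13, 1.75 for Igk, 1.83 for Hddc3, -1.03 for Zfp945, -2.14 for Tnfsf13os and -1.22 for Hspb7. Hsd3b3 stood at -3.90 and Iglv1 at 2.77 in the same way, and Iglv1, GasKO vs WT, was at 3.33 without WT replicate 3 and 4.80 without WT replicate 1. A second probe set stood at 0.58 for Igk and at -0.07 for Hspb7.

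Interferon response genes rose together in GasKO (camera adjusted p = 5.4e-10, and adjusted p = 0.627 with an estimated correlation). Of 31 measured, 21 rose, 1 fell and 9 were not called, and adjusted over the list alone 24 rose and 2 fell. Ifit1 rose 10.8-fold (log2 3.44, SE 0.50, adjusted p = 0.00186, and log2 2.85 without WT replicate 3), Oasl2 4.93-fold, Ifit2 3.11-fold and Psmb9, a subunit of the immunoproteasome, 1.64-fold. The chemokine gene Cxcl10, named after its values were seen, fell by 0.81 on the log2 scale. The list score was 1.09 in GasKO replicate 1, 0.78 in replicate 3 and -0.02 in replicate 2, against -0.67 to -0.28 in WT. The call held when replicate 2 or any other single array was left out, with adjusted p between 1.2e-19 and 1.5e-07.

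MHC class II genes, which present antigen to helper T cells, rose in GasKO (adjusted p = 2.6e-08, and adjusted p = 0.363 with an estimated correlation). Of 7 measured, 6 rose, and adjusted over the list alone all 7 did. Cd74, the invariant chain gene, rose from 11.37 ± 0.06 to 12.00 ± 0.05 (log2, SD, n = 3), H2-Eb1 rose by 0.78, H2-Ab1 by 0.74 and H2-Oa by 2.01 on the log2 scale, the last from near background. Plasma cell markers rose (adjusted p = 5.7e-04, and adjusted p = 0.567 with an estimated correlation), with 5 of 7 called, also when adjusted over the list alone. WT replicate 3 had the lowest plasma cell score, -1.42 against -0.55 and -0.20 in the other WT arrays, and without it the list median was 1.19 in place of 1.64 (adjusted p = 4.8e-04). Among the genes were Jchain, 3.13-fold, Mzb1, 5.90-fold, Igha, 1.94-fold, and Derl3, 1.83-fold from near background. B cell markers rose (adjusted p = 0.00897, and adjusted p = 0.627 with an estimated correlation). Ms4a1, Cd79a and Cr2 were the 3 of 6 called, at 2.19-fold, 2.24-fold and, from near background, 1.53-fold, and 4 were called when adjusted over the list alone. Myeloid markers rose (adjusted p = 0.00172, and adjusted p = 0.627 with an estimated correlation), with 4 of 17 called and 5 adjusted over the list alone. These were led by Cd163 (log2 0.67), Lyz2 (0.52), Mpeg1 (0.58) and Cd14 (0.39). Adipocyte markers rose as a list (adjusted p = 0.0385, and adjusted p = 0.627 with an estimated correlation), with 0 of 6 called, 4 when adjusted over the list alone, and Fabp4 at log2 0.79 (adjusted p = 0.066). That call was lost without WT replicate 3 or GasKO replicate 2, with adjusted p up to 0.192.

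Ribosome biogenesis genes fell in GasKO (adjusted p = 8.2e-06, and adjusted p = 0.567 with an estimated correlation). Of 20 measured, 10 fell and none rose, and 12 fell adjusted over the list alone. Gnl3, a nucleolar GTPase gene, changed by -0.50, the helicase gene Ddx21 by -0.52, Nop58 by -0.46 and Ppan by -0.38 on the log2 scale. S phase genes fell (adjusted p = 1.1e-05, and adjusted p = 0.567 with an estimated correlation), with 6 of 28 called and 13 adjusted over the list alone. Mcm2 and Mcm5, subunits of the replicative helicase, fell by 0.63 and 0.29 on the log2 scale, the polymerase gene Pold1 by 0.46 and Uhrf1 by 0.48. Mitosis genes went the other way as a list (adjusted p = 0.00325, and adjusted p = 0.845 with an estimated correlation). Only Plk1, a mitotic kinase gene, was called of 29, at log2 0.62, and none was when adjusted over the list alone, while Mki67 stood at log2 0.34 (SE 0.12, adjusted p = 0.0993). Without WT replicate 2 the mitosis list was not called (adjusted p = 0.104).

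Heat shock genes fell (adjusted p = 1.9e-04, and adjusted p = 0.567 with an estimated correlation), with 5 of 13 called and 7 adjusted over the list alone. Among these chaperone genes Chordc1 changed by -0.42, Dnaja1 by -0.32, Hspd1 by -0.26 and Hspe1 by -0.25 on the log2 scale. Genes of hypoxia and glycolysis fell (adjusted p = 0.00608, and adjusted p = 0.567 with an estimated correlation), with 4 of 17 called, also when adjusted over the list alone. Bnip3, a mitophagy gene, changed by -0.54, the angiogenic factor gene Vegfa by -0.57, the hexokinase gene Hk2 by -0.43 and the lactate dehydrogenase gene Ldha by -0.25. Without WT replicate 2 that list was not called (adjusted p = 0.0732).

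Camera did not call lists of epithelial cell types in GasKO vs WT, although single members changed. Among stem cell markers (adjusted p = 0.218, but called as falling by fry at 0.0385), Lgr5 fell by 0.94 and Rgmb by 0.49 on the log2 scale, and the other 9 of 11 were not called. Goblet cell markers had an adjusted p of 0.677: Ern2, an endoplasmic reticulum stress sensor gene, fell 2.68-fold, Atoh1, the secretory lineage factor gene, fell 1.18-fold, Spink4 rose 1.28-fold and 14 of 17 were not called. Among colonocyte markers (adjusted p = 0.711), Ceacam20 fell 2.95-fold, the carbonic anhydrase gene Car4 fell 1.24-fold, the uroguanylin gene Guca2b rose 2.43-fold and 16 of 19 were not called. Tac1 and Reg4 rose 1.61-fold and 1.66-fold among enteroendocrine markers (adjusted p = 0.982). Wnt targets had an adjusted p of 0.614 with 1 of 11 called, and EGFR and MAPK genes 0.056 with 0 of 15.

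Among distal colon genes (adjusted p = 0.197, but called as falling by fry at 0.0446), Fxyd4 fell 3.11-fold and the sodium channel subunit genes Scnn1g and Scnn1b 2.94-fold and 1.63-fold, with 6 of 9 not called. Of xenobiotic genes (adjusted p = 0.153), Ces2a fell 2.70-fold, Abcb1a 1.51-fold and Cyp2c55 1.49-fold, and Cyp3a13 rose 1.46-fold. In the NF-kB list (adjusted p = 0.946), Tnfaip3, an inhibitor of the pathway, fell 1.52-fold, and Vcam1 and Ptgs2 rose 1.58-fold and 1.49-fold. The STAT3 targets Pim1 and Socs3 rose 1.90-fold and 1.59-fold, with an adjusted p of 0.218 for their list. In the BMP list (adjusted p = 0.565), Bmp5 rose 1.61-fold, and Chrdl1 rose 1.30-fold but stood at -0.07 when its probe sets were averaged. The fatty acid translocase gene Cd36 rose 1.90-fold and Acadl fell 1.15-fold in the oxidation list (adjusted p = 0.794). Asns rose 1.72-fold and Xbp1 fell 1.15-fold among unfolded protein genes (adjusted p = 0.711), and the clock genes Per1 and Npas2 fell 1.88-fold and 1.97-fold (list adjusted p = 0.106). Pdgfra, Dcn and Col14a1 rose 1.30-fold, 1.19-fold and 1.19-fold among fibroblast markers (list adjusted p = 0.264).

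The count of called genes was 888 without GasKO replicate 1, and between 926 and 1375 without any other array. Of the 69 called list members that the rule named, 43 kept their call in each of those 9 fits. Over 20 alternatives in all, the calls of Col14a1, Per1, Npas2, Hspe1, Dcn and Dnaja1 were kept in 6, 7, 8, 8, 9 and 9. Cr2 kept its call in 6 of 18 and Xbp1 in 7 of 19. Of the lists camera called, fry did not call the B cell, myeloid, mitosis and adipocyte lists (adjusted p = 0.0857, 0.0857, 0.357 and 0.205). With probe sets averaged, Lgr5 stood at log2 -0.46, Rgmb at -0.28, Ddx21 at -0.34, Tac1 at 0.35 and Pim1 at 1.41, Acadl was no longer called at -0.10, and Mcm5 stood at -0.53 with probe sets designed for 1 transcript.

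**Figure D2:**
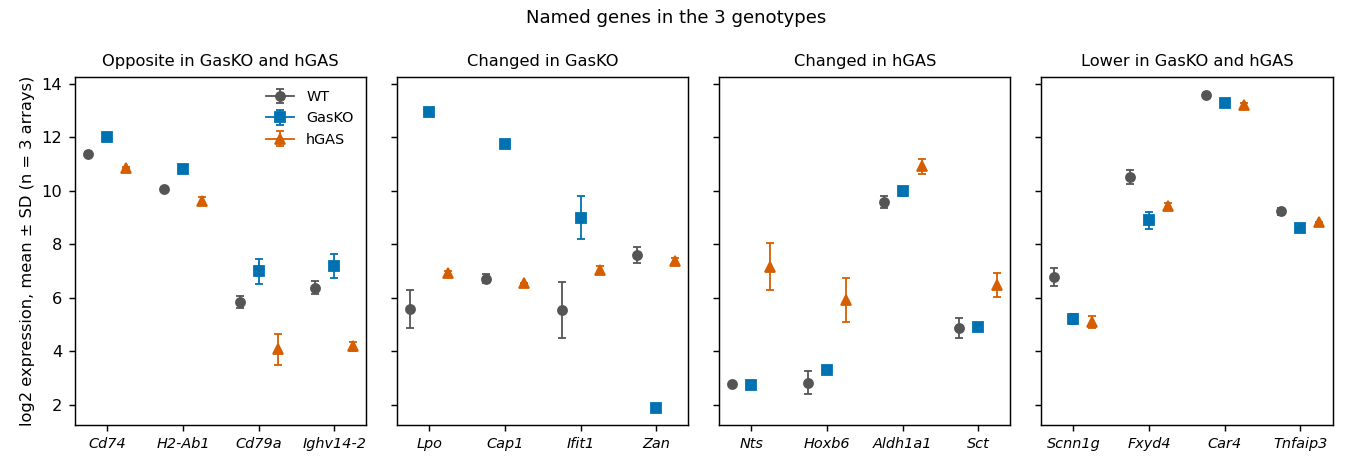
Expression (log2, mean ± SD, n = 3 arrays) of named genes in WT, GasKO and hGAS. Cd74, H2-Ab1, Cd79a and Ighv14-2 were called in opposite senses in GasKO and hGAS against WT, Scnn1g, Fxyd4, Car4 and Tnfaip3 fell in both, and the middle panels show genes called in GasKO or in hGAS.

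In hGAS mucosa, B cell and MHC class II genes fell as lists against wild type, though neither call held with an estimated correlation (adjusted p = 0.241 and 0.0946). Fcmr, the IgM receptor gene, fell 4.92-fold from 6.26 ± 0.51 in WT to 3.96 ± 0.01 in hGAS (log2, SD, n = 3), and the antibody heavy chain gene Ighv14-2 fell 4.54-fold from 6.37 ± 0.26 to 4.19 ± 0.17. Nts, which encodes the gut peptide neurotensin, rose 20.7-fold from near background at 2.78 ± 0.03 to 7.15 ± 0.88. Hoxb6, a positional homeobox gene, rose 8.55-fold from 2.81 ± 0.43 to 5.90 ± 0.83, while Scnn1g, a sodium channel gene of the distal colon, fell 3.20-fold from 6.75 ± 0.34 to 5.08 ± 0.22.

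This comparison asks what goes with the hGAS transgene. It called 131 of 11274 genes, 72 that rose and 59 that fell, with a median absolute log2 change of 0.64. At least a 2-fold change was seen in 27 and 13 of them. The groups did not overlap in 17.7% of genes, where chance gives 10%.

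Further rises were Osr2, a transcription factor gene, 10.3-fold (SE 0.60 in log2), Prkg2, a cGMP-dependent kinase gene, 9.35-fold (SE 0.63), and the intestinal homeobox gene Isx, 7.46-fold (SE 0.57). Prap1 rose 7.45-fold, the carboxylesterase gene Ces1g 6.82-fold, the sulphate transporter gene Slc13a1 5.39-fold, Hsd17b13 4.97-fold and Car8 4.18-fold. Further falls were H2-Ob, 3.87-fold, Tmem267, 3.63-fold, and the B cell receptor genes Cd79a and Cd79b, 3.38-fold and 2.98-fold. Ccr6, a chemokine receptor gene, fell 2.90-fold, Speer4cos 2.26-fold and Fxyd4 2.17-fold. Osr2, Hoxb6, Prap1 and Hsd17b13 were near background in WT, and Fcmr, H2-Ob and Ccr6 were near background in hGAS. Of these 20 genes, Nts, Hoxb6, Prap1, Fcmr, Ighv14-2 and Scnn1g kept their call when any 1 array was left out, and the other 14 lost it in at least 1 of the 9 fits, Isx in each, with adjusted p up to 0.145. With probe sets averaged, Hsd17b13 stood at log2 1.16, and Slc13a1 was no longer called at 1.37. Osr2 was at log2 2.53 without hGAS replicate 2 and 4.09 without hGAS replicate 3, Prkg2 at 2.48 and Isx at 2.20 without WT replicate 3, both no longer called, and Prap1 at 3.64 with probe sets designed for 1 transcript.

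MHC class II genes fell in hGAS (adjusted p = 3.3e-12, and adjusted p = 0.0946 with an estimated correlation). Of 7 measured 5 fell, and all 7 fell adjusted over the list alone. Cd74 changed by -0.53 (SE 0.05), H2-Eb1 by -0.54 (SE 0.06), H2-Ab1 by -0.44 (SE 0.07) and H2-Ob by -1.95 (SE 0.27) on the log2 scale. B cell markers fell (adjusted p = 9.1e-09, and adjusted p = 0.241 with an estimated correlation), with Fcmr, Cd79a and Cd79b called of 6, and all 6 adjusted over the list alone. Plasma cell markers went the other way as a list (adjusted p = 0.00193, and adjusted p = 0.546 with an estimated correlation). None of these 7 was called, 4 were adjusted over the list alone, and Jchain stood at log2 1.10 (adjusted p = 0.0955) and at 0.73 without WT replicate 3. That array had the lowest plasma cell score, -1.42 against -0.55 and -0.20 in the other WT arrays, and without it the list median was 0.35 in place of 0.59 (adjusted p = 0.011). The list was not called with probe sets designed for 1 transcript (adjusted p = 0.0537), and hGAS replicate 1, at -0.41, lay within the WT range. NF-kB targets fell (adjusted p = 0.00101, and adjusted p = 0.104 with an estimated correlation), with Tnfaip3 (log2 -0.41) and the adhesion gene Icam1 (-0.81) called of 14, and 4 adjusted over the list alone.

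Distal colon genes fell in hGAS (adjusted p = 2.7e-06, and adjusted p = 0.0946 with an estimated correlation). Scnn1g and Fxyd4 were the 2 of 9 called, 5 fell adjusted over the list alone, and Hoxb13 stood at log2 -0.39 (adjusted p = 0.116). The list of proximal colon genes had too few measured members to test, and of its 4 members Hoxb6 and Osr2 rose. Xenobiotic genes rose as a list (adjusted p = 0.0392, and adjusted p = 0.546 with an estimated correlation), with the retinal dehydrogenase gene Aldh1a1 (2.53-fold) and the glutathione transferase gene Gsta4 (1.58-fold) called of 10, and 5 rising and 1 falling adjusted over the list alone. Among enteroendocrine markers (adjusted p = 0.493), the secretin gene Sct rose 3.03-fold beside Nts. Car1 rose 1.39-fold and Car4 fell 1.28-fold among colonocyte markers (adjusted p = 0.705).

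S phase genes fell as a list in hGAS (adjusted p = 2.8e-05, and adjusted p = 0.546 with an estimated correlation), with 0 of 28 called and 3 adjusted over the list alone. Mcm7 stood at log2 -0.22 (adjusted p = 0.089) and Uhrf1 at -0.41 (adjusted p = 0.0900). Mitosis genes were not called as a list (adjusted p = 0.0735) and no member was. The same held for stem cell markers (adjusted p = 0.982, median -0.06 but mean 0.02) and Wnt targets (adjusted p = 0.536), of which 2 and 1 rose adjusted over the list alone. EGFR and MAPK genes fell as a list (adjusted p = 0.0391, and adjusted p = 0.695 with an estimated correlation), with 0 of 15 called, 1 adjusted over the list alone, and Dusp4, a phosphatase gene of the pathway, at log2 -0.63 (adjusted p = 0.0603).

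Cholesterol synthesis genes fell as a list (adjusted p = 2.7e-06, and adjusted p = 0.546 with an estimated correlation), with 0 of 17 called, 1 adjusted over the list alone and Srebf2 at log2 -0.27 (adjusted p = 0.0598). Genes of fatty acid oxidation rose as a list (adjusted p = 0.00114, and adjusted p = 0.546 with an estimated correlation). None of 17 was called, 5 rose and 1 fell adjusted over the list alone, and Acaa2 stood at log2 0.40 (adjusted p = 0.089). Clock genes fell as a list (adjusted p = 0.0115, and adjusted p = 0.546 with an estimated correlation). Of 16 only Cry1, a repressor of the clock, was called, and it rose by 0.46 on the log2 scale, while 2 rose and 7 fell adjusted over the list alone. Heat shock genes rose as a list (adjusted p = 0.0161, and adjusted p = 0.546 with an estimated correlation) with 0 of 13 called under either adjustment. BMP genes fell as a list (adjusted p = 0.0392, and adjusted p = 0.552 with an estimated correlation), with Id4 (log2 -0.43) called of 14, and 1 rising and 4 falling adjusted over the list alone. Smooth muscle markers fell as a list (adjusted p = 0.0384, and adjusted p = 0.725 with an estimated correlation) with 0 of 15 called under either adjustment. The smooth muscle, BMP, EGFR and MAPK, heat shock, xenobiotic and clock lists each lost their call in at least 1 of the 9 fits without 1 array, with adjusted p up to 0.355, 0.148, 0.415, 0.123, 0.123 and 0.0550.

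The bactericidal lectin genes Reg3b and Reg3g, named for this comparison after their values were seen, varied widely and were not called in hGAS vs WT, at log2 5.49 (SE 1.37, adjusted p = 0.0955) and 4.42 (SE 0.93, adjusted p = 0.0603). Their list, the epithelial defence genes, had an adjusted p of 0.169 with a median of -0.03 and a mean of 1.28. The bile acid transporter gene Slc51a was at log2 3.49 (SE 0.76, adjusted p = 0.0695), at 2.38 without hGAS replicate 2 and at 4.33 without hGAS replicate 3, and it was called in both of those fits.

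Of the 14 lists camera called in hGAS vs WT, fry called only the MHC class II, B cell, distal colon and NF-kB lists (adjusted p = 0.00221, 0.0199, 0.00789 and 0.0178). Of the 19 called list members that the rule named, 7 kept their call in each of the 9 fits without 1 array. Icam1 was called in 1 of those fits, Tnfaip3, H2-Ab1 and Cry1 in 2, Gsta4 in 3 and Id4 in 0, with the highest adjusted p at 0.156 for Id4. GasKO arrays enter this contrast only through the shared estimate of the spread, so part of any fall without 1 array may be lost precision. The count of called genes was lower whichever array was left out. Without hGAS replicates 1 to 3 it was 26, 60 and 98. Without WT replicates 1 to 3 it was 77, 104 and 78, and without GasKO replicates 1 to 3 it was 61, 79 and 65. It was 27 in a fit of only the 6 arrays and 58 without the filter, and with a regional score of proximal minus distal colon genes as a covariate, an alternative chosen after seeing the data, limma called 0 genes, with 696 at an unadjusted p under 0.05 in place of 1596. Of the 131 genes, 127 kept their sense with that covariate, while the median change went from 0.643 to 0.387 and the median SE from 0.0969 to 0.243. The score was positive in all hGAS arrays and negative in all others. Its genes include Osr2, Hoxb6, Scnn1g and Fxyd4, which were themselves called in this comparison. The covariate thus takes out part of the change under test, so the loss of calls cannot separate region from genotype.

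**Figure D3:**
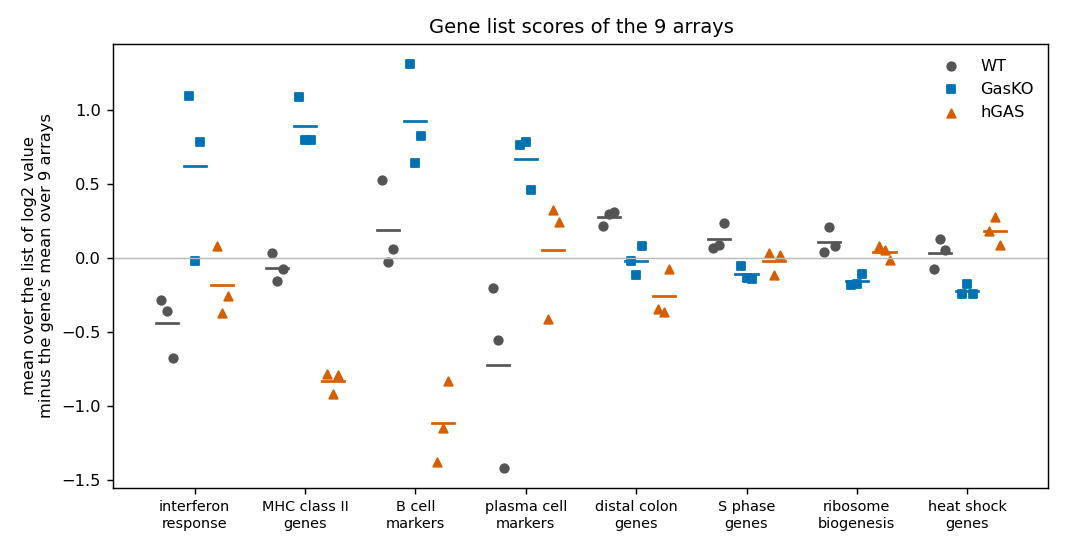
Scores of 8 gene lists in each array, in log2 units, as the mean over the list of a gene's value minus its mean over the 9 arrays; points are arrays and lines are group means. MHC class II scores are 0.80 to 1.09 in GasKO, -0.16 to 0.04 in WT and -0.92 to -0.78 in hGAS.

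Set directly against each other, hGAS mucosa had lower MHC class II and B cell and higher heat shock gene expression than GasKO mucosa, and none of these list calls held with an estimated correlation (adjusted p = 0.171, 0.413 and 0.413). Cd74 fell 2.24-fold from 12.00 ± 0.05 in GasKO to 10.84 ± 0.03 in hGAS (log2, SD, n = 3), and Cd79a fell 7.59-fold from 6.99 ± 0.47 to 4.06 ± 0.59. Reg3b rose 425-fold from background at 2.98 ± 0.11 to 11.71 ± 1.53, but WT arrays lay in between with a wide spread, 6.21 ± 3.31. Hsd3b3 rose 17.1-fold from 6.05 ± 0.38 to 10.15 ± 0.10.

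This contrast sets carriers of the transgene against mice without gastrin, and it is also the test of the difference between the effects of the other comparisons. It called 1866 genes, 907 that rose and 959 that fell, with a median absolute log2 change of 0.47 and at least 2-fold changes in 152 and 162. The groups did not overlap in 36.7% of genes, where chance gives 10%. Of the 1866, 1029 were also called in GasKO vs WT in the matching sense, 96 in hGAS vs WT, 18 in both and 759 in neither. The comparisons share arrays, so part of this overlap is built in.

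Zan was 45.4-fold higher in hGAS, Tnfsf13os 21.2-fold, Hsd3b2 21.1-fold and Aadac 15.6-fold, and all but Aadac were near background in GasKO. Zfp945 rose 23.4-fold, also from near background, but stood at -1.55 on the log2 scale with probe sets designed for 1 transcript. Reg3g rose 45.3-fold, Nts 21.6-fold and Prkg2 20.4-fold, each from near background in GasKO. St6galnac1 fell 74.6-fold, Lpo 64.7-fold, Cap1 37.3-fold, Gdpd3 22.9-fold, Krt12 12.4-fold, Hddc3 12.2-fold, Igk 12.2-fold and Serpina1b 11.9-fold. Of these, St6galnac1, Krt12 and Serpina1b were near background in hGAS. Apoc2, an apolipoprotein gene, fell 10.2-fold and Abhd1 9.49-fold. Each of these 20 genes kept its call when any 1 array was left out. With probe sets averaged, the log2 change was -3.19 for St6galnac1, -1.80 for Hddc3, -1.23 for Igk, 2.19 for Tnfsf13os, 0.92 for Zfp945, 3.15 for Prkg2 and 4.85 for Hsd3b3. Without hGAS replicate 3 Reg3b stood at 9.60 and Reg3g at 6.50, and Reg3g at 4.90 without hGAS replicate 2.

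All 7 MHC class II genes fell (adjusted p = 3.5e-11, and adjusted p = 0.171 with an estimated correlation), and so did all 6 B cell markers (adjusted p = 1.0e-06, and adjusted p = 0.413 with an estimated correlation). These counts were the same adjusted over the list alone, and H2-Eb1 changed by -1.32, H2-Aa by -1.26, Fcmr by -2.56, Cd79b by -2.56 and Cr2 by -1.44 on the log2 scale, with Fcmr and Cr2 near background in hGAS. Interferon genes fell (adjusted p = 3.1e-07, and adjusted p = 0.657 with an estimated correlation), 14 of 31, with 1 that rose, Xaf1, named after its values were seen, and 22 and 1 adjusted over the list alone. The score of GasKO replicate 2, -0.02, lay within the hGAS range of -0.37 to 0.08, apart from the other GasKO arrays. The immunoproteasome genes Psmb8 and Psmb9 changed by -0.97 and -0.72, Oas1a by -0.94 and Trim30a by -1.52. Myeloid markers fell (adjusted p = 3.7e-05, and adjusted p = 0.657 with an estimated correlation), 7 of 17 under either adjustment, with Lyz2 at -0.68, Mpeg1 at -0.63, Cd163 at -0.58 and Csf1r at -0.30. NF-kB targets fell (adjusted p = 0.0424, and adjusted p = 0.413 with an estimated correlation), with 4 of 14 called, 4 falling and 1 rising adjusted over the list alone, and Icam1 at -0.94, Ptgs2 at -0.62 and Vcam1 at -0.54. The NF-kB call was lost without GasKO replicate 3 or hGAS replicate 1, with adjusted p up to 0.108.

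Heat shock genes rose (adjusted p = 6.6e-06, and adjusted p = 0.413 with an estimated correlation), 7 of 13, and 10 adjusted over the list alone, with Hsph1 at log2 0.98, Chordc1 at 0.59, Dnaja1 at 0.52 and Hspe1 at 0.35. Ribosome biogenesis genes rose as a list (adjusted p = 0.00317, and adjusted p = 0.657 with an estimated correlation), with 6 that rose and 1 that fell of 20, and 11 and 1 adjusted over the list alone. Among these Ppan stood at log2 0.46, Gnl3 at 0.45, Ddx21 at 0.39 and Nop56 at 0.32. Xenobiotic genes rose (adjusted p = 0.00317, and adjusted p = 0.439 with an estimated correlation), 7 of 10 under either adjustment, with Ces2a at 2.43-fold, Aldh1a1 at 1.91-fold, Gsta4 at 1.71-fold and the quinone reductase gene Nqo1 at 1.57-fold. Respiratory chain genes rose slightly (adjusted p = 0.0366, and adjusted p = 0.632 with an estimated correlation), 5 of 19 under either adjustment, with Ndufa4 at log2 0.35 and Cox6c at 0.19. The respiratory call was lost without GasKO replicate 1 or hGAS replicate 1, with adjusted p up to 0.0897.

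Camera did not call lists of proliferation and stem cells in hGAS vs GasKO. S phase genes had an adjusted p of 0.225, with Pold1 (log2 0.45), Ccne2 (0.47) and Mcm2 (0.36) called of 28, and mitosis genes one of 0.137 with 1 of 29 called. Stem cell markers had an adjusted p of 0.242, but were called as rising by fry (adjusted p = 0.0498), with Lgr5 (log2 0.88), Rgmb (0.53) and Prom1 (0.60) higher in hGAS and 8 of 11 not called. The Wnt targets Ephb3 and Axin2 fell by 0.55 and 0.52 on the log2 scale, in a list with an adjusted p of 0.497. Among enterocyte markers of the small intestine (adjusted p = 0.255), Alpi, the intestinal alkaline phosphatase gene, rose 6.59-fold, the fatty acid binding gene Fabp2 2.84-fold and Apob 1.44-fold. Sct, the secretin gene, and Tph1, the serotonin synthesis gene, rose 2.98-fold and 2.58-fold, and Reg4 fell 2.03-fold (list adjusted p = 0.658). Ern2 and Atoh1 rose 2.71-fold and 1.34-fold and Tff3 and Fcgbp fell 1.16-fold and 1.38-fold among goblet markers (adjusted p = 0.512). Ceacam20 rose 2.53-fold, Slc51a 11.3-fold from near background and Slc51b 2.37-fold, and Guca2b fell 1.80-fold, among colonocyte markers (adjusted p = 0.588). Without hGAS replicate 2 or 3 Slc51a stood at log2 2.39 or 4.34 in place of 3.50. Epithelial defence genes had an adjusted p of 0.438, with Reg3b and Reg3g higher, Il18 lower and 6 of 9 not called. The homeobox genes Hoxa13 and Hoxb13 of the distal colon list fell 1.52-fold and 1.33-fold (list adjusted p = 0.216).

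Further lists with single called members were not called by camera in hGAS vs GasKO. BMP genes had an adjusted p of 0.0948 and were called as falling by fry (adjusted p = 0.0498), with 2 that rose and 6 that fell of 14. Chrdl1 changed by -0.67, Bmp5 by -0.57, Id4 by -0.48 and Smad7 by -0.39 on the log2 scale, and with probe sets averaged Chrdl1 stood at -0.28 and Smad7 at -0.26. The clock genes Npas2, Nfil3 and Cry1 rose by 1.22, 0.99 and 0.43 and Hlf changed by -0.92 (list adjusted p = 0.792). Vegfa rose by 0.60 and Bnip3 by 0.29 among 4 of 17 genes of hypoxia and glycolysis that rose (adjusted p = 0.216). The immediate early genes Ccn2, Dusp1 and Jun rose by 0.81, 0.51 and 0.42 (adjusted p = 0.827), and the fibroblast markers Pdgfra, Dcn and Col14a1 changed by -0.37, -0.29 and -0.23 (adjusted p = 0.658). Asns fell by 0.60 and Xbp1 rose by 0.23 among unfolded protein genes (adjusted p = 0.658).

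Of the lists camera called in this comparison, fry did not call the interferon list (adjusted p = 0.104). The hGAS vs GasKO count was 1219 without GasKO replicate 3 and 1232 without GasKO replicate 1, and 58 of the 95 called list members that the rule named kept their call in each of the 9 fits without 1 array. Over 20 alternatives in all, Col14a1 kept its call in 8, Fabp2 in 10 and Apob in 12. With probe sets averaged, Psmb8 stood at log2 -0.52, Lgr5 at 0.44, Rgmb at 0.31 and Axin2 at -0.26, and Apob and Ddx21 were no longer called at 0.26 and 0.20, nor was Pold1, at 0.21, with probe sets designed for 1 transcript. Over all 3 genotypes the F test called 1785 genes, 1098 without GasKO replicate 3 and 1126 without GasKO replicate 1.

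Some genes changed in opposite senses in GasKO and in hGAS, each against WT. Named after their values were seen, the B cell attracting chemokine gene Cxcl13 rose by 1.56 in GasKO and changed by -0.95 in hGAS on the log2 scale, Clu, the clusterin gene, by 0.63 and -0.77, and Coro1a, an actin regulator of leukocytes, by 0.65 and -0.74. In all, 15 genes rose in GasKO and fell in hGAS, where independent lists would share 3.91, and among them were Cd74, H2-Aa, H2-Ab1, H2-Eb1, Cd79a, Ccr6 and Ighv14-2. The reverse held for 3 genes (3.95 for independent lists), Hsd3b2, Col8a1 and Smim5. Another 14 genes rose in both (4.78 for independent lists), among them Hsd17b13, Nupr1 (log2 0.84 in GasKO and 1.28 in hGAS) and Adamdec1 (0.52 and 0.79), and 15 fell in both (3.23), among them Scnn1g, Fxyd4, Car4, Tnfaip3 and Hif1a (-0.54 and -0.32).

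The log2 changes of the GasKO and hGAS comparisons correlated at r = 0.118 across genes, which are not independent replicates. In 100 simulations of all 9 arrays, unchanged groups that shared 3 simulated WT arrays gave r = 0.503 ± 0.043 (SD). Their covariance was 0.0104 ± 0.0014, close to the measured 0.0114. Genes were drawn independently, so this SD leaves out the correlation between genes in the real arrays. The simulations gave no shared calls, but with no change simulated hardly any could arise, so that count cannot judge the shared calls measured. The 3 WT arrays cannot be split further, so part of the excess of genes changed in both genotypes in the same sense may come from the shared controls.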

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

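The regional score as covariate was the only alternative here chosen after seeing the result. With it hGAS vs WT had 0 genes called, hGAS vs GasKO 221 and the F test 1093. The score was built in part from genes called in hGAS vs WT, so it takes out part of that change. For the 131 genes of hGAS vs WT the median change went from 0.643 to 0.387 and the median SE from 0.0969 to 0.243, and 127 kept their sense. A replicate block gave 283 genes for hGAS vs WT, 126 of the 131 among them, 1558 for GasKO vs WT and 2087 for hGAS vs GasKO. Deviations from group means correlated at -0.0056 to 0.267 for arrays of the same number, over 0.1 in all GasKO and hGAS pairs but not in all pairs with WT, and at -0.292 to 0.113 for other numbers. Without the block the hGAS vs WT count was 58 with no filter, 27 with only the 6 arrays compared and 340 at an adjusted p under 0.1. Using all probe sets gave 2182 calls in GasKO vs WT, 2925 in hGAS vs GasKO and 2824 across the genotypes. Asking also for at least 1.5-fold left 559 in GasKO vs WT, 73 in hGAS vs WT and 722 in hGAS vs GasKO.

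Chrdl1 in GasKO vs WT was -0.0704 with the mean of probe sets. Zfp945 was 1.46 in GasKO vs WT and -1.55 in hGAS vs GasKO with only probe sets without an s, x or a ending. The cause was not tested. Of gene lists, hGAS vs WT had 9 with these probe sets and 4 with fry. With an estimated correlation 0 lists were called in GasKO vs WT, 0 in hGAS vs WT and 0 in hGAS vs GasKO, from 11, 14 and 9.

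Without 1 array, GasKO vs WT ran from 888 (GasKO replicate 1) to 1375 (hGAS replicate 2) and hGAS vs WT from 26 (hGAS replicate 1) to 104 (WT replicate 2). Likewise hGAS vs GasKO ran from 1219 (GasKO replicate 3) to 1996 (WT replicate 3), and the F test from 1098 to 1750 for the same arrays. Quantile normalisation gave 1382, 131 and 1892 calls, and median centring 1389, 122 and 1859. GCRMA had already normalised the arrays by quantiles, so both settings could change little.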

Other observations

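The reading of the test on probe sequences, the neighbour ratios without immune genes and for the largest changes, and the sorting of splits by the GasKO arrays were chosen after seeing results, and the other tests in this part before. Lymphocyte genes outside the B cell and MHC class II lists were lower in hGAS vs WT in 13 of 13 cases, though none was called. Among the abundant ones, Cd52 stood at log2 -0.33 and Ptprc, the CD45 gene, at -0.23. In GasKO vs WT 10 of these 13 genes rose, with a median log2 change of 0.70. In hGAS vs GasKO 12 fell, with a median of -0.95.

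The strong changes of GasKO vs WT could come from DNA of another mouse strain. Near Gast 19% of 200 genes were called, against 12.0% elsewhere. Other stretches of 200 genes ranged from 3% to 26% with a median of 11%, so the share near Gast was within their range. These 355 stretches overlapped each other, as only 11252 genes had a position, and they may hold strain segments themselves. Their range therefore cannot decide whether the stretch around Gast stood out. Pairs of genes near but not directly beside each other were then counted, leaving out the 200 genes nearest to Gast. They were called together 1.28 times as often as in shuffled orders (permutation p = 0.001, the smallest that 1000 shufflings allow), and 1.29 times with immune genes left out. As many top ranked genes of hGAS vs WT gave 1.06 (permutation p = 0.001), and for the largest changes the ratios were 1.72 in GasKO and 1.44 in hGAS. Strain segments could give the higher ratios in GasKO, but gene families lying together could also give grouping, which hGAS showed too. Stretches of 20 genes with the most called changes of at least 2-fold in GasKO were of both kinds. In 1 of them all 6 such genes were immunoglobulin light chain genes. Another held Cd109 (log2 1.72), Col12a1 (-1.49), Ibtk (-1.01), Tpbg and Me1 (1.20), which moved both ways. These stretches were picked for their counts, so they cannot single out a cause. Only 131 genes were called in hGAS vs WT, so most of its top ranked genes were not called. Such a set may be less grouped whatever the cause, so the difference in ratios cannot single out strain segments. Of the 69 called GasKO genes changed at least 2-fold with a second expressed probe set, 24.6% had one that moved by under 0.25 of the change or the other way, against 25% of 4 in hGAS (Fisher's exact p = 1), so probe sequences that hybridize differently cannot be told apart from a change in expression.

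The hGAS changes may reflect a piece of colon nearer to the caecum. Across 127 genes, which are not independent replicates, hGAS vs WT changes followed the regional score within groups at r = 0.759 (permutation p = 0.0556, highest of 216 orders 0.782). The score ran from 0.549 to 2.01 in hGAS, from -1.03 to -0.644 in WT and from -0.538 to -0.440 in GasKO. This slope within groups thus rests mainly on the 3 hGAS arrays. A transgene effect that differs in strength between them could give the same r, so region and genotype cannot be told apart.

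Less lymphoid tissue in the hGAS samples may explain the lower B cell and MHC class II genes. The separate lymphocyte genes had a median log2 change of -0.23, below all 10000 random lists, whose medians lay between -0.078 and 0.091 in 95% of cases. Random lists were drawn gene by gene, so they are narrower than lists of genes that move together, and none of the 13 genes was called. No tissue was sorted, so an effect on the lymphocytes themselves was not tested. In GasKO vs WT the same 13 genes had a median log2 change of 0.70, above all 10000 random lists. The amount of lymphoid tissue therefore cannot be told apart from genotype for the immune genes that rose in GasKO.

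The real grouping gave 1366, 131 and 1866 calls in the pairwise comparisons, 1 of 10 splits of 3 against 3 arrays in each, and the highest other split gave 0. These splits are too few for a share under 0.05. For the F test, 1 of 100 splits, the real one with 1785 calls, was highest. The 4 other splits that kept the GasKO arrays together gave 961 to 1233, and the 95 that parted them gave 0 to 13.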
